A study of Drosophila melanogaster with 8 samples.

How the data were processed

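Transcripts were measured by sequencing of polyA RNA from whole females, in 4 control and 4 mutant libraries. Per the labels' protocols, RNA was extracted with Trizol from 8 collections of 12 females per genotype, pairs of extractions were pooled and purified on columns to give 4 samples per genotype, and libraries followed standard Illumina protocols. The authors deposited 1 table of read counts per gene, with whole numbers in 8 columns, and these counts were not normalized before deposit, since they sum to a different total in each library. The submitters' processing notes name the genome build dm3 and the tool DESeq, without a version or a role. The aligner, the counting program, the annotation and the use of strand are not given in the sources used here. Without known strand handling, reads of overlapping or antisense genes cannot be told apart, and reads of near-identical copies may have been split or dropped.

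Groups and replicate numbers were taken from the sample titles, and columns were matched to samples by name, with 0 columns left unmapped. Of 12083 rows, 1 names no gene (CG00000, 0.0154% to 0.0176% of the counts of a library) and was left out of totals and tests. The other 12082 rows carry CG numbers, which were matched to gene symbols through the RefSeq gene table of the Release 6 assembly. A current locus tag matched 11482 of them and an older synonym 456, while 84 matched several genes and 31 none, and these stayed under their CG number. A further 29 rows are transcript forms of a gene, 26 of them of Dscam1 and 3 of mod(mdg4). Because the authors' build differs from Release 6, only chromosome arms and neighbourhood were taken from that table and no coordinates are given. The smallest total of a row over the 8 libraries was 10 counts, and 228 rows repeat another row exactly.

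The tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and tables and plots were made in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. Counts were filtered with edgeR's filterByExpr at its defaults (minimum count 10), which left 10525 genes, and scaled with TMM. Mutant and control were compared with edgeR's robust quasi-likelihood test without covariates, two-sided, and p-values were adjusted with the Benjamini-Hochberg method at a threshold of 0.05. A standard error is the absolute log2 fold change divided by the square root of the test's F value. CPM values are counts divided by the TMM-scaled library size, given as mean ± SD with n = 4 per genotype. The level of 3 counts serves as the floor for a count of 0, and it covers counting error only. Libraries of 1 genotype differed by more than sampling noise in all pairs (chi-square per degree of freedom 10.4 to 36.3), so none were merged as repeated runs of 1 library. That each is a replicate of its own rests on the labels, by which every library pools 2 collections. On simulated data with 200 planted changes drawn from these libraries' means and sizes, the comparison of mutant with control over 10525 genes recovered 34% of changes of 1.25-fold, 66% at 1.5-fold, 86% at 2-fold and 96% at 4-fold, with 8 false calls among 149 (5.37%). Changes of 1.25-fold were therefore often missed in that simulation. Far more genes passed in the real data (2063), which makes the adjusted threshold less strict there, so these shares may understate the recovery.

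Gene lists numbering 45 were fixed before the data were examined, from general knowledge of fly tissues and pathways, and 4 members caught by a symbol pattern by mistake were dropped. Each was compared with the other genes by camera on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over the 45 lists. The same test with a correlation estimated per list called none of them, while 9 passed with the preset value. fry, which tests whether a list's genes move one way on balance without comparing them with other genes, called only the ecdysone list.

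The rule for named genes was also fixed before the data were examined. It takes Hr78 and btl, the 12 largest rises and 12 largest falls among genes past the threshold whose genotypes do not overlap and whose mean is at least 2 CPM, and up to 4 members past the threshold with the smallest adjusted p from each list. It names 167 genes, of which 120 were chosen for the report in the rule's own order. One of these is not reported here, and the others are printed. The genes chosen are the largest changes, all named members of lists past camera's threshold and the first 2 of every other list. This share was set after the values had been seen. An earlier choice had left out genes whose calls were lost when a library was removed, which made the printed genes look steadier, and it was replaced by this order. Bace, CG12374, Mgstl and Alp9 were added after their values were seen, and the checks for single libraries far from the others and for changes of call ran over all of these genes.

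The alternatives fixed beforehand were RLE and upper quartile scaling, no filter on low counts, the replicate number as a block, each library left out in turn, DESeq2, limma-voom, other thresholds, and camera with an estimated correlation or fry for the lists. Those chosen after seeing the data were counting identical rows and transcript forms once, an offset per library for exonic length (a loess curve on the log2 length of the longest transcript, known for 99.1% of tested genes) and the member counts of lists without single libraries. Alternatives planned for normalized values or for a table of the authors' comparison were not run, because the table holds counts.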

Results

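RNA was sequenced from whole adult females of Drosophila melanogaster of 2 genotypes, with 4 libraries per genotype. Both genotypes carried a transgene that expressed Hr78 (DHR78), a gene for a nuclear receptor, through the driver of btl (breathless), the gene of the tracheal FGF receptor. The mutants also carried a pair of different mutant alleles of Hr78, and the controls were matched to them in background. The series is titled for adult functions of this receptor, and the comparison asks which transcripts of adult females differed when Hr78 was mutant in flies that carried the transgene. The females were 1 week old and had been raised on food with 8% yeast and 9% sugar. Each genotype gave 8 collections of 12 females, and RNA of 2 collections was pooled for each library.

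Total counts were 28106635, 21849314, 20851045 and 19544675 in control replicates 1 to 4 and 33054191, 26654328, 24814861 and 22608378 in mutant replicates 1 to 4. At these depths 3 counts corresponded to 0.0908 to 0.153 CPM (the counts-per-million scale). The gene with the most counts in every library, eEF1alpha1 (a translation elongation factor), took 1.54% to 1.66% of them. Between 572 and 731 rows of the table had a count of 0 in 7 of the libraries, and 29 rows did in mutant replicate 2. The first principal component of log2 CPM held 48.5% of the variance and separated the genotypes, and the second held 15.5% and set mutant replicate 2 apart from the others.

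Hr78 transcripts were lower in the mutant, at 71.6 ± 1.71 CPM against 123 ± 4.22 CPM in the control (mean ± SD, n = 4 each), which is 58.0% of the control level. Every mutant library (69.3 to 73.4 CPM) lay below every control library (118 to 127 CPM). The log2 fold change of Hr78 (CG7199, on arm 3L in the Release 6 annotation) was -0.79 with a standard error of 0.04 and an adjusted p of 4.90e-06 (edgeR quasi-likelihood test, Benjamini-Hochberg). An exact two-sided permutation test of the CPM values gave p = 0.0286, the smallest value that 4 libraries against 4 allow. The transcript of btl (CG32134, on 3L), whose driver was used, was at 6.35 ± 0.681 CPM in the control and 6.14 ± 0.622 CPM in the mutant, with a log2 fold change of -0.05, a standard error of 0.11 and an adjusted p of 0.790 by edgeR. Reads from the transgene and from the chromosomal gene are not separated in these counts, so the level of Hr78 checks the genotype labels only in part.

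**Figure D1:**
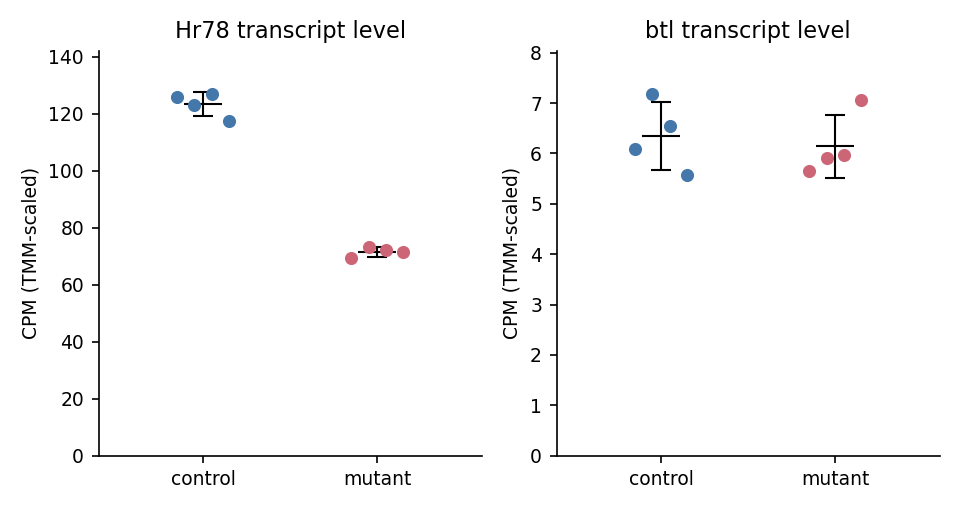
CPM of Hr78 (left) and btl (right) in each of the 4 control and 4 mutant libraries (points), with the mean and SD of each group (bars). Hr78 lay at 71.6 CPM in the mutant and 123 CPM in the control, while the groups overlapped for btl.

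Transcripts of many genes differed between the genotypes. Of 10525 genes tested, 2063 (19.6%) passed an adjusted p of 0.05 (edgeR quasi-likelihood, Benjamini-Hochberg). Of these, 890 were higher and 1173 lower in the mutant. Most of these differences were small, with a median absolute log2 fold change of 0.35. At least 1.5-fold changes were found for 526 genes (243 higher, 283 lower) and at least 2-fold changes for 236 genes (117 higher, 119 lower). The 4 mutant libraries all lay on one side of the 4 control libraries for 1916 of the 2063 genes, and for 25% of all tested genes, where chance gives 2.86%. The balance of directions depended on the scaling, since 43.1% of the calls were higher with TMM and 63.2% (1499 higher, 872 lower) with upper quartile scaling. Without mutant replicate 2, 1702 genes passed the threshold (716 higher, 986 lower), of which 1579 were among the 2063. Leaving out any 1 library lowered the count, to between 1476 and 1702 genes. A call lost without a library therefore does not by itself single out that library.

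Among genes with a mean level of at least 2 CPM, CG31832 had the largest rise, from 2.44 ± 1.30 to 40.1 ± 3.75 CPM (log2 fold change 4.00, standard error 0.29). MtnD, a metallothionein gene, rose from 2.95 ± 0.885 to 20.2 ± 1.2 CPM, and Cyp6a17, a cytochrome P450 gene, from 2.92 ± 0.744 to 14.2 ± 0.750 CPM. CG40198 rose by 2.79 and CG2961 by 2.70 on the log2 scale. The other 7 of the 12 largest rises were those of Cyp4d21, CG14191, Cda9, BomBc3, CG1304, CG6761 and GNBP-like3, with log2 fold changes between 2.13 and 3.15. BomBc3 encodes a Bomanin, a secreted peptide of the Toll immune response, and its mutant libraries spread widely (43.2 ± 25 CPM against 7.60 ± 1.21 CPM). The adjusted p of these 12 genes lay between 5.31e-06 and 0.00663 (edgeR).

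The largest falls were those of CG10154, from 13.5 ± 4.98 to 0.155 ± 0.0933 CPM, and CG10725, from 141 ± 49.6 to 2.91 ± 0.690 CPM (log2 fold change -5.59, standard error 0.35). The mutant mean of CG10154 lay at about the level of 3 counts per library, so its fitted log2 fold change of -6.47 is imprecise. CG7900 fell from 11.3 ± 1.38 to 0.588 ± 0.197 CPM, with an adjusted p of 2.46e-06 (edgeR), the smallest of all genes. Jon66Ci and CG18180, which encode serine proteases of the midgut, fell by 3.03 and by 2.35, and CG7298, a chitin-binding peritrophin-like gene, fell by 2.36 on the log2 scale. Reepl1, CR33255, CG34166, CG17999 and Ir76a(CG8533) were also among the 12 largest falls, with log2 fold changes between -3.14 and -2.44. CG13032 had a log2 fold change of -3.84 and an adjusted p of 0.0281 (edgeR), and the call was not kept in every alternative. Mutant replicate 2 was at 2.46 CPM of CG13032 and the other mutants at 0.0395 to 0.0611 CPM. Without that library its log2 fold change was -7.44 and its adjusted p 8.34e-08 (edgeR), while leaving out any 1 of the other 7 libraries gave an adjusted p of 0.0584 to 0.0744, the replicate block 0.0730 and no filter on low counts 0.0518.

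**Figure D2:**
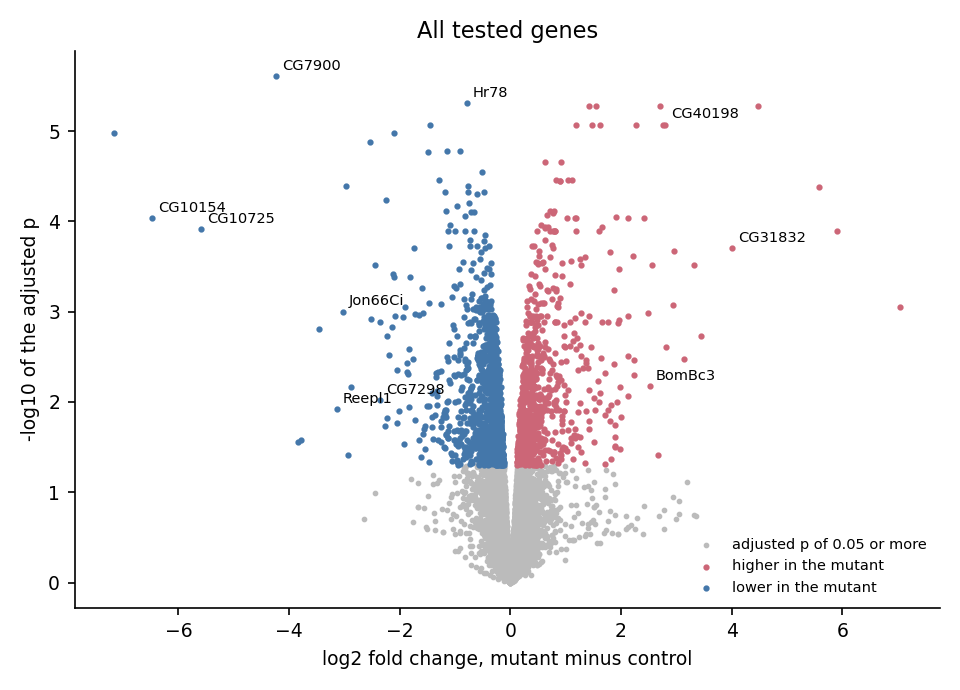
Log2 fold change (mutant minus control, horizontal) against the -log10 of the adjusted p (vertical) of the 10525 tested genes, with 890 genes higher (red) and 1173 lower (blue) in the mutant. Named points are Hr78 and some of the genes with the largest changes, and points beyond CG31832 on the right or CG10154 on the left had a mean level under 2 CPM.

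Among genes of secreted midgut serine proteases more fell than rose in the mutant. Of 39 tested, 19 fell, 3 rose and 17 did not pass the threshold (3 higher and 21 lower when adjusted over the list alone). Jon25Bi fell from 227 ± 64.4 to 59.2 ± 7.06 CPM, CG18180 from 252 ± 83.6 to 49.7 ± 9.64 CPM, CG18179 from 18.4 ± 5.28 to 4.34 ± 1.18 CPM and Jon66Ci from 17.5 ± 6.07 to 2.12 ± 0.874 CPM. The list differed from the other genes with an adjusted p of 0.000933 (camera with a preset correlation of 0.01, Benjamini-Hochberg over 45 lists), and adjusted p = 0.845 with an estimated correlation. Its median log2 fold change was -0.50. When mutant replicate 2 was left out, 19 members fell and 4 rose.

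The other digestive lists did not pass camera's threshold, though single members changed. Of 26 genes of midgut lipases and sterol carriers, 4 fell and none rose (0 higher and 4 lower when adjusted over the list alone; camera adjusted p 0.252). CG17192 fell from 101 ± 27.2 to 27.6 ± 7.19 CPM and CG6296 from 26.3 ± 16.3 to 6.4 ± 0.87 CPM. The call of CG6296 was lost without mutant replicate 2 (adjusted p 0.0608) or mutant replicate 4 (0.0517, edgeR), and the members that fell numbered 2 without control replicate 1 or mutant replicate 1 and 1 without mutant replicate 4. Of 15 genes of the peritrophic matrix and gut mucins, 4 fell and 1 rose, the same numbers as when adjusted over the list alone (camera adjusted p 0.256). Crys rose from 6.83 ± 0.608 to 12.3 ± 1.71 CPM and CG7298 fell from 103 ± 18.7 to 20.3 ± 13.2 CPM. Of 22 genes listed as digestive carbohydrases, 5 rose and 3 fell (9 higher and 3 lower when adjusted over the list alone; camera adjusted p 0.317), and 5 fell without mutant replicate 2. Amy-d, an amylase gene, rose from 11.3 ± 0.819 to 28.7 ± 5.61 CPM and CG9701 rose by 0.90 on the log2 scale. One of the 3 that fell was Bace, an aspartic protease placed in this list in error, which went from 1113 ± 347 to 311 ± 40.0 CPM. Amy-d has a near-identical copy, Amy-p, and many Jonah proteases are close paralogs, so the split of reads between such copies is uncertain.

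Among gut regulators, 1 of 12 enteroendocrine genes rose and 2 fell (2 higher and 3 lower when adjusted over the list alone; camera adjusted p 0.788). The peptide hormone gene ITP rose from 20.8 ± 1.66 to 25.2 ± 0.951 CPM and pros, a transcription factor gene of enteroendocrine cells, fell from 5.71 ± 1.35 to 3.71 ± 0.386 CPM. The call of pros was lost with an offset for transcript length (adjusted p 0.267, edgeR) and without control replicate 2 (0.0513), mutant replicate 1 (0.0628) or mutant replicate 4 (0.0518). Of 13 genes of intestinal progenitors and growth signals, 2 fell (2 lower when adjusted over the list alone; camera adjusted p 0.186), peb by 0.71 and mira by 0.77 on the log2 scale.

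Among genes of antimicrobial peptides and other immune effectors more rose than fell. Of 47 tested, 16 rose, 5 fell and 26 did not pass the threshold (21 higher and 6 lower when adjusted over the list alone). The Bomanin genes BomT3 and BomS3 rose from 32.2 ± 1.90 to 56.6 ± 9.52 CPM and from 73.9 ± 2.98 to 139 ± 30.2 CPM. The 5 members that fell were lysozyme genes (LysC, LysD, LysE, LysS and LysX), which are known as digestive enzymes of the midgut, while LysP rose by 0.36 on the log2 scale. LysE fell from 109 ± 26.9 to 36.6 ± 3.11 CPM, and reads of LysC, LysD and LysE, which are close copies, may be split between them. The list had a camera adjusted p of 0.000933 and a median log2 fold change of 0.45, and adjusted p = 0.845 with an estimated correlation. Its median exonic length (611 bases) was the shortest of all lists. With an offset for transcript length its camera adjusted p was 0.0170, and its mean log2 fold change went from 0.49 to 0.37. Without control replicate 3, 10 members rose, and without mutant replicate 1 or mutant replicate 3, 3 fell. Without mutant replicate 2, 16 members rose and 4 fell.

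Genes of metal homeostasis rose where they changed, with 11 of 29 higher and none lower in the mutant (also 11 and 0 when adjusted over the list alone). Besides MtnD, the metallothionein genes MtnB and MtnC rose from 4.71 ± 1.35 to 17.4 ± 3.32 CPM and from 6.05 ± 1.59 to 11.2 ± 1.18 CPM, and ZnT41F, a zinc transporter gene, rose by 0.77 on the log2 scale. The list had a camera adjusted p of 0.0264 and a median log2 fold change of 0.05, and adjusted p = 0.845 with an estimated correlation. Without mutant replicate 1 the camera adjusted p was 0.0922. In the fit without mutant replicate 2, 10 members rose.

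Genes of detoxification changed in both directions. Among 77 cytochrome P450 genes 20 rose and 12 fell (20 higher and 17 lower when adjusted over the list alone; camera adjusted p 0.429), and 7 fell without control replicate 1. Besides Cyp6a17, Cyp4d14 rose from 7.69 ± 0.698 to 15.7 ± 1.53 CPM. Among 34 genes of glutathione S-transferases 9 rose and 4 fell (11 higher and 4 lower when adjusted over the list alone; camera adjusted p 0.154). GstD3 fell from 40.1 ± 4.85 to 18 ± 0.792 CPM, whereas GstE9 rose from 24.7 ± 1.45 to 43.7 ± 3.30 CPM. Among 31 genes of UDP-glycosyltransferases 6 rose and 1 fell (8 higher and 1 lower when adjusted over the list alone; camera adjusted p 0.131), with Ugt49B1 and Ugt302C1 rising by 0.64 and 0.34 on the log2 scale. Of 17 genes of the oxidative stress response 3 rose and 2 fell (5 higher and 3 lower when adjusted over the list alone; camera adjusted p 0.447). GstD1, which is in this list and in that of the transferases, fell from 609 ± 34.2 to 359 ± 29.6 CPM, and the thioredoxin gene Trx2 rose from 208 ± 1.99 to 254 ± 14 CPM.

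Of 28 tested genes of the ecdysone pathway and of nuclear receptors, a list that leaves out Hr78, 11 fell, none rose and 17 did not pass the threshold (0 higher and 12 lower when adjusted over the list alone). MsrA, a methionine sulfoxide reductase gene also known as Eip71CD, fell from 233 ± 40.3 to 62.0 ± 13.4 CPM. Eip75B, a nuclear receptor gene of the ecdysone response, fell from 88.9 ± 4.07 to 68.2 ± 5.06 CPM. The gene of the ecdysone receptor partner usp fell from 135 ± 2.60 to 116 ± 4.07 CPM, and br, an ecdysone response gene, from 15.1 ± 1.93 to 10.3 ± 0.645 CPM. The list had a camera adjusted p of 0.000933 and a median log2 fold change of -0.23, and adjusted p = 0.498 with an estimated correlation. With an offset for transcript length the camera adjusted p was 0.0865, while the list's mean log2 fold change went from -0.43 to -0.36, and br did not pass the threshold (adjusted p 0.0667, edgeR). Without mutant replicate 2, 8 members fell.

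Of 21 tested genes of tracheal fate and tube formation 5 fell and 1 rose, with the same numbers when adjusted over the list alone, and none rose without control replicates 2, 3 or 4 or mutant replicate 1. The tracheal regulator gene trh fell from 4.58 ± 0.900 to 2.77 ± 0.297 CPM, and serp, a chitin deacetylase gene, from 4.79 ± 1.46 to 2.49 ± 0.206 CPM. The junction gene pyd, in the row of CG31349, fell from 217 ± 7.73 to 162 ± 10.7 CPM. The list had a camera adjusted p of 0.0357 and a median log2 fold change of -0.13, and adjusted p = 0.845 with an estimated correlation. With the length offset its adjusted p was 0.141 and its mean log2 fold change -0.23, against -0.29 without it. The adjusted p was 0.0686 to 0.123 without control replicate 1, control replicate 2, mutant replicate 1 or mutant replicate 2, and 0.0850 with the replicate block. The gene of dpy, a very long matrix protein, was at 25.2 ± 2.46 CPM in the control and 18.3 ± 0.785 CPM in the mutant, and its log2 fold change of -0.46 became 0.06 with the length offset. Of 10 circadian clock genes 3 fell and none rose (0 higher and 4 lower when adjusted over the list alone; camera adjusted p 0.415). The clock gene tim fell from 224 ± 16.2 to 152 ± 22.5 CPM and vri from 112 ± 5.19 to 84.5 ± 5.70 CPM, while the list's median log2 fold change was 0.01 and its mean -0.11. Of 27 cuticle protein genes 4 rose and 4 fell, also when adjusted over the list alone (camera adjusted p 0.565), with Cpr72Ec rising from 3.62 ± 1.01 to 11.5 ± 0.432 CPM. Lcp1, a cuticle gene known from larvae, was at 0.978 ± 0.256 CPM in the mutant and at 0.0113 CPM in the control, below the level of 3 counts, and passed the threshold. Without control replicate 3 or mutant replicate 3, 2 cuticle genes fell. The median log2 fold change of the cuticle list was -0.13 and its mean 0.13.

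**Figure D3:**
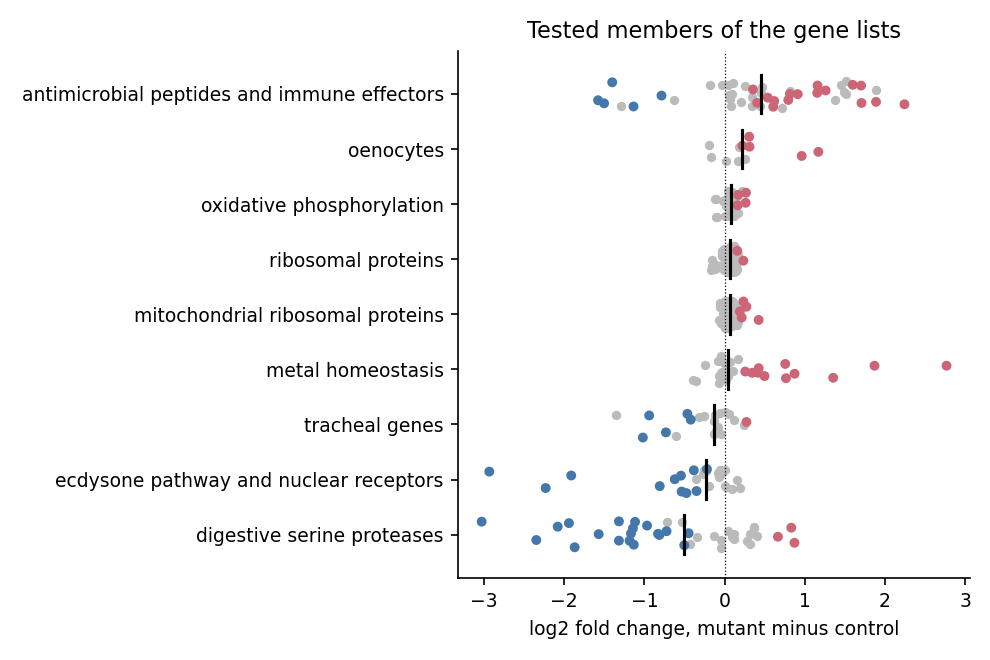
Log2 fold change (mutant minus control) of each tested member of the 9 gene lists that passed camera with a preset correlation of 0.01, with members past an adjusted p of 0.05 in red (higher) or blue (lower) and the median of each list as a black bar. The medians ran from -0.50 for the digestive serine proteases to 0.45 for the immune effectors.

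Of the lists of lipid metabolism, that of oenocytes passed camera's threshold. Of 11 oenocyte genes of very long chain fatty acid and hydrocarbon synthesis 5 rose and none fell, also when adjusted over the list alone. CG17562 and CG17560, which encode fatty acyl-CoA reductases, rose from 10.3 ± 0.455 to 23.2 ± 3.77 CPM and from 48.8 ± 9.01 to 95.3 ± 16.0 CPM. Cyp4g1, the P450 gene of hydrocarbon synthesis, rose from 5974 ± 671 to 7417 ± 555 CPM and FASN3, a fatty acid synthase gene, from 329 ± 24.7 to 384 ± 27.2 CPM. The oenocyte list had a camera adjusted p of 0.0357 and a median log2 fold change of 0.22, and adjusted p = 0.845 with an estimated correlation. It was not past the threshold with upper quartile scaling (0.0759), nor without control replicate 2, control replicate 4, mutant replicate 1 or mutant replicate 3 (0.0619 to 0.123), and 2, 2, 3 and 2 members rose without these libraries. The call of Cyp4g1 was lost without the same 4 libraries (adjusted p 0.0592 to 0.0738, edgeR). That of FASN3 was lost without control replicate 2, control replicate 4, mutant replicate 3 or mutant replicate 4 (0.0709 to 0.107) and without a filter on low counts (0.0539). The members that rose numbered 6 without mutant replicate 2.

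In triglyceride synthesis 4 of 14 genes fell, also when adjusted over the list alone (camera adjusted p 0.345), and 2 fell without control replicate 1, control replicate 4, mutant replicate 2 or mutant replicate 4. The acyltransferase genes CG1946 and Dgat2 fell from 3.99 ± 1.24 to 1.254 ± 0.157 CPM and from 1.63 ± 0.256 to 0.809 ± 0.187 CPM. Of 29 genes of fatty acid synthesis and elongation 6 rose and 1 fell (9 higher and 2 lower when adjusted over the list alone; camera adjusted p 0.429). Without control replicate 2, control replicate 4, mutant replicate 1 or mutant replicate 3 the members that rose numbered 2, 3, 3 and 2. The elongase gene CG5326 fell by 0.60 on the log2 scale, and Zw, the gene of glucose-6-phosphate dehydrogenase, rose by 0.41.

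Of 12 genes of lipid droplets and lipolysis 2 rose and 1 fell, also when adjusted over the list alone (camera adjusted p 0.633), with Ldsdh1 rising by 0.56 on the log2 scale. Lsd-2, a perilipin gene, was at 813 ± 23.7 CPM in the control and 704 ± 10.3 CPM in the mutant, and its call was lost with the length offset (adjusted p 0.0835, edgeR). Of 15 genes of lipoproteins and lipid transport 2 rose and 3 fell (3 higher and 3 lower when adjusted over the list alone; camera adjusted p 0.722), and the list's median of -0.03 and mean of 0.02 differ in sign. GLaz, a lipocalin gene, rose by 0.43 on the log2 scale, while the call of apolpp, the gene of the main lipoprotein (1847 ± 99.7 against 1482 ± 33.2 CPM), was lost with the length offset (adjusted p 0.332, edgeR). Of 27 genes of beta-oxidation 1 rose and 4 fell, also when adjusted over the list alone (camera adjusted p 0.401), with CG4586 falling by 0.45 on the log2 scale. Of 13 genes listed for peroxisome biogenesis 3 rose, also when adjusted over the list alone (camera adjusted p 0.345). Pex19 rose from 67.5 ± 1.24 to 75.7 ± 1.52 CPM. Cat, the gene of the enzyme catalase rather than of a biogenesis factor, rose from 344 ± 27.1 to 411 ± 28.3 CPM. The call of Cat was lost without control replicates 2, 3 or 4 or mutant replicates 1 or 3 (adjusted p 0.0519 to 0.0647, edgeR), and 1 peroxisome gene rose without each of these 5 libraries.

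Of 20 genes of glycolysis and sugar storage 7 rose and 1 fell, also when adjusted over the list alone (camera adjusted p 0.154). UGP rose from 292 ± 15.9 to 359 ± 12.1 CPM, and Tps1, the trehalose synthesis gene, fell from 755 ± 49.6 to 645 ± 24.1 CPM. The number that rose was 1 to 4 without control replicates 2, 3 or 4 or mutant replicates 1, 2 or 4. Of 21 genes listed for the tricarboxylic acid cycle 1 rose and 3 fell, also when adjusted over the list alone (camera adjusted p 0.429). The citrate synthase gene kdn fell by 0.27 on the log2 scale. Idh, an isocitrate dehydrogenase gene, rose by 0.16, a call that was lost without control replicate 3 (adjusted p 0.0504) or mutant replicate 3 (0.0534, edgeR), and 1 gene of the list fell without control replicates 1 or 4 or mutant replicates 2, 3 or 4. Of 23 genes of sugar and amino acid transporters 4 rose and 2 fell (5 higher and 2 lower when adjusted over the list alone; camera adjusted p 0.317), with Eaat2 rising by 0.51 and sbm falling by 0.40 on the log2 scale. Of 23 genes of insulin, TOR and FOXO signalling 2 rose and 3 fell (3 higher and 4 lower when adjusted over the list alone; camera adjusted p 0.345), and the list's median of -0.09 and mean of 0.01 differ in sign. The alpha-glucosidase gene tobi in that list rose from 8.52 ± 3.79 to 33.8 ± 6.32 CPM, while the call of Sesn, the sestrin gene (209 ± 8.83 against 182 ± 4.84 CPM), was lost with the length offset (adjusted p 0.130, edgeR).

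The lists of ribosomal and respiratory chain genes were shifted upward in the mutant by small amounts, few of their genes passed the threshold, and the shift was not kept with an offset for transcript length. Of 87 ribosomal protein genes 2 rose, RpS12 (1101 ± 79.9 against 1296 ± 85.3 CPM) and RpL29 (468 ± 23.3 against 522 ± 18.2 CPM), and none of the 87 passed when adjusted over the list alone. Of 73 mitochondrial ribosomal protein genes 5 rose (3 higher when adjusted over the list alone), among them mRpS21, mRpL14, mRpS23 and mRpS31 by 0.43, 0.27, 0.24 and 0.21 on the log2 scale. Of 34 genes of oxidative phosphorylation 4 rose (2 higher when adjusted over the list alone), COX7C by 0.27, COX8 by 0.26, sun by 0.17 and ND-PDSW by 0.16. The camera adjusted p was 0.00639 for the ribosomal, 0.00313 for the mitochondrial ribosomal and 0.0322 for the oxidative phosphorylation list, with median log2 fold changes of 0.07, 0.06 and 0.08, and adjusted p = 0.845 with an estimated correlation for each. Without mutant replicate 1 the adjusted p of these lists was 0.207, 0.0922 and 0.207. The ribosomal list was also lost without control replicate 2 (0.170) or control replicate 4 (0.0771), and that of oxidative phosphorylation without control replicate 2 (0.171), control replicate 3 (0.0532) or control replicate 4 (0.0729). Without mutant replicate 1, 2 ribosomal genes fell and none rose, none rose without control replicates 2 or 4 or mutant replicate 3, and 4 rose without control replicate 3. Without mutant replicate 2, 1 ribosomal, 3 mitochondrial ribosomal and 4 oxidative phosphorylation genes rose.

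Fold changes followed transcript length, with a Spearman rho of -0.36 across genes, which are not independent replicates. The median log2 fold change was 0.09 in the fifth of genes with the shortest exonic length and -0.12 in the fifth with the longest. The slope of log2 CPM per doubling of length was positive in the 4 controls (0.0329 to 0.0516) and negative in the 4 mutants (-0.0858 to -0.0216). It was -0.0858 in mutant replicate 1, the library with the most counts, and -0.0336 to -0.0216 in the other mutants. Without mutant replicate 1 the ribosomal, mitochondrial ribosomal and oxidative phosphorylation lists were not past camera's threshold, as given above. With an offset for length the adjusted p of the ribosomal, mitochondrial ribosomal and oxidative phosphorylation lists was 0.438, 0.263 and 0.891, and their mean log2 fold changes turned from 0.06, 0.08 and 0.08 to -0.02, -0.02 and -0.002. The muscle and photoreceptor lists, in contrast, passed only with this offset (adjusted p 0.0181 each, higher in the mutant) or, for muscle, also without control replicate 1 (0.0378). RpS12, RpL29, mRpL14, mRpS23, mRpS31, COX8, sun and ND-PDSW then lost their calls (adjusted p 0.0713 to 0.801, edgeR). With that offset 1546 genes passed the threshold (783 higher, 763 lower), of which 1271 were among the 2063.

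Several of these small differences also lost their calls with a library left out. RpS12 lost its call without control replicates 2 or 4 or mutant replicates 1 or 3 (adjusted p 0.0633 to 0.0766, edgeR), and RpL29 without any library but control replicate 3 (0.0601 to 0.112), while its log2 fold change stayed at 0.13 to 0.19 over the 8 fits. For mRpS31 these were all but control replicate 3 and mutant replicate 4 (0.0646 to 0.104), and 3 mitochondrial ribosomal genes rose without any 1 of the same 6 libraries. The call of sun was lost without control replicates 1, 2 or 4 or mutant replicates 1 or 3 (0.0585 to 0.0953). That of ND-PDSW was lost without control replicates 2, 3 or 4 or mutant replicates 1, 3 or 4 (0.0696 to 0.115). Without a filter on low counts the calls of ND-PDSW (0.0624), RpL29 (0.0504) and mRpS31 (0.0572) were lost as well. Of the oxidative phosphorylation genes 2 rose without control replicate 2, control replicate 4, mutant replicate 1 or mutant replicate 3.

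**Figure D4:**
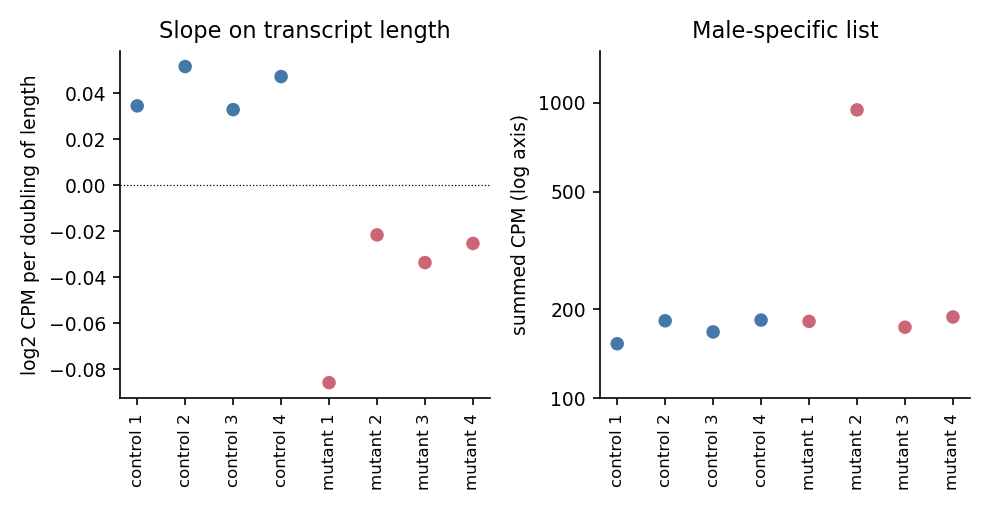
Left, slope of log2 CPM (deviation from the mean of all libraries) per doubling of exonic length in each library, positive in the 4 controls and negative in the 4 mutants, most of all in mutant replicate 1. Right, summed CPM of the 59 rows of the testis and male accessory gland list on a log axis, at 947 CPM in mutant replicate 2 and between 153 and 189 CPM in the other 7 libraries. In those 7 libraries most counts of the list were of twe, Acp95EF and Mst85C, which were counted in every library.

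No list of marker genes of other tissues in this paragraph passed camera's threshold with all libraries and the main settings. Of 25 muscle genes 9 rose and 3 fell (11 higher and 3 lower when adjusted over the list alone; camera adjusted p 0.195, and 0.0181 with the length offset). TpnC25D and Mlc2, genes of a troponin C and a myosin light chain, rose by 0.59 and 0.31 on the log2 scale. Of 17 genes of the Malpighian tubule 4 fell, also when adjusted over the list alone (camera adjusted p 0.109), and 1 fell without control replicates 1 or 3 or mutant replicates 2 or 4. This list passed camera, as lower, without a filter on low counts, with the replicate block and without control replicates 2 or 4 or mutant replicate 3 (adjusted p 0.0177 to 0.0484). The potassium channel gene Irk3 fell from 40.2 ± 4.02 to 25.1 ± 1.72 CPM. The cotransporter gene Ncc69 (59.2 ± 3.48 against 50.3 ± 4.01 CPM) lost its call with upper quartile scaling (adjusted p 0.0562), with the length offset (0.259), and without control replicates 1, 3 or 4 or mutant replicates 2, 3 or 4 (0.0588 to 0.0734, edgeR). Of 12 fat body genes 3 rose and 2 fell (3 higher and 4 lower when adjusted over the list alone; camera adjusted p 0.813), with Adh rising from 946 ± 65.5 to 1463 ± 80.7 CPM. Of 13 hemocyte genes 1 rose and 1 fell, also when adjusted over the list alone (camera adjusted p 0.633). The prophenoloxidase gene PPO3 rose by 0.83 on the log2 scale. The call of the collagen gene vkg (142 ± 29.9 against 79.4 ± 20.6 CPM) was lost with the length offset (adjusted p 0.0871) and without any library but control replicate 4 and mutant replicate 1 (0.0654 to 0.0940, edgeR). Its log2 fold change was -0.69 with the length offset and -0.84 in the main fit.

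In the nervous system 3 of 25 photoreceptor genes rose, also when adjusted over the list alone (camera adjusted p 0.195, and 0.0181 with the length offset). The rhodopsin gene ninaE was at 1801 ± 81.7 CPM in the control and 2115 ± 152 CPM in the mutant, and inaD, a scaffold gene of phototransduction, at 29.7 ± 3.01 and 36.1 ± 2.66 CPM. The call of ninaE was lost with the length offset (adjusted p 0.0543) and without control replicates 2 or 4 or mutant replicate 3 (0.0513 to 0.0641, edgeR), and that of inaD without control replicates 2 or 4 or mutant replicates 1 or 3 (0.0592 to 0.0794). The log2 fold change of ninaE was 0.19 with the length offset and 0.23 in the main fit. No photoreceptor gene rose without control replicate 2, control replicate 4 or mutant replicate 3, 1 rose without mutant replicate 1 and 6 without mutant replicate 4. Of 16 neuronal genes 2 rose and 2 fell, also when adjusted over the list alone (camera adjusted p 0.915). Csp fell by 0.18 and comt rose by 0.29 on the log2 scale, a call of comt that was lost without mutant replicate 3 (adjusted p 0.0508, edgeR).

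No list of the female reproductive system passed camera's threshold with all libraries and the main settings. For comparison with the member counts, 19.6% of all tested genes passed the threshold. Of 30 germline genes 2 rose and 2 fell (1 higher and 2 lower when adjusted over the list alone; camera adjusted p 0.457), with stau falling by 0.29 on the log2 scale. The call of cup (637 ± 15.1 against 571 ± 19.6 CPM) was lost with upper quartile scaling (adjusted p 0.0789), with the length offset (0.196), and without control replicates 2 or 4 or mutant replicates 2 or 3 (0.0513 to 0.0765, edgeR). Of 24 eggshell genes none passed the threshold either way, and the median log2 fold change was -0.14 (camera adjusted p 0.429). Of 4 genes of yolk proteins and the yolk receptor 1 fell, also when adjusted over the list alone (camera adjusted p 0.154). That gene was yl, the yolk receptor, which fell from 1915 ± 203 to 1172 ± 216 CPM, and without control replicate 2, 3 of the 4 fell and the yolk and eggshell lists passed camera as lower (adjusted p 0.0114 each). Of 11 genes of the spermatheca and reproductive tract 1 rose and 2 fell, also when adjusted over the list alone (camera adjusted p 0.729), and the list's median of 0.00 and mean of -0.07 differ in sign. Send1, a spermathecal protease gene, fell from 16.8 ± 3.54 to 8.42 ± 1.66 CPM, and CG32834 rose by 0.69 on the log2 scale.

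Transcripts known from males were raised in 1 library. The 59 rows of the list of testis and male accessory gland genes summed to 947 CPM in mutant replicate 2 and to 153 to 189 CPM in the other libraries. Most counts in those other libraries were of twe, Acp95EF and Mst85C, which were counted in every library. They held 2219, 951 and 746 of the list's 4104 counts in control replicate 1, against 2894, 1577 and 883 of 25828 in mutant replicate 2. The sums thus understate the excess of the remaining rows in mutant replicate 2. Of the 59 rows 10 had enough counts to be tested, and none passed the threshold, also when adjusted over the list alone (median log2 fold change 0.51, camera adjusted p 0.195). Without mutant replicate 2 the median was 0.08 and the mean 0.05, against a mean of 0.80 with it.

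None of the remaining lists passed camera's threshold, and most of their calls were lost with a single library left out. Of all tested genes 19.6% passed the threshold. Of 25 genes of the heat shock and unfolded protein response 1 rose, Hsp68 (none when adjusted over the list alone; camera adjusted p 0.565), and the list's median of -0.06 and mean of 0.03 differ in sign. The call of Hsp68 (7.36 ± 0.899 against 9.79 ± 1.07 CPM) was lost without control replicates 2 or 4 or mutant replicates 2 or 3 (adjusted p 0.0666 to 0.0862, edgeR). Of 26 genes of the cell cycle and DNA replication 1 rose, PCNA, and 1 fell, Mcm6 (none when adjusted over the list alone; camera adjusted p 0.789). The call of PCNA was lost with the length offset (adjusted p 0.300) and without any library but control replicate 2 and mutant replicate 3 (0.0599 to 0.0793, edgeR). That of Mcm6 was lost with upper quartile scaling (0.147), with the length offset (0.0598) and without any library but mutant replicate 4 (0.0551 to 0.117). The log2 fold change of Mcm6 was -0.12 with the length offset and -0.13 in the main fit. Of 9 genes of the hypoxia response 1 rose and 1 fell, also when adjusted over the list alone (camera adjusted p 0.447). The call of sima, the gene of the hypoxia factor (228 ± 6.63 against 194 ± 9.61 CPM), was lost with the length offset (adjusted p 0.150, edgeR). That of the globin gene glob1 was lost with the length offset (0.244), with RLE scaling (0.0524), without a filter on low counts (0.0584), with identical rows counted once (0.0501) and without any library but control replicate 2 (0.0720 to 0.127). Of 11 genes of the Turandot and JAK/STAT stress list 1 rose and 1 fell, also when adjusted over the list alone (camera adjusted p 0.447), and the list's median of 0.09 and mean of -0.08 differ in sign. Tep2, a thioester protein gene, rose by 0.31 on the log2 scale. The call of the receptor gene dome (143 ± 10.8 against 113 ± 14.7 CPM) was lost with the length offset (adjusted p 0.152) and without control replicates 1, 2 or 4 or mutant replicate 3 (0.0531 to 0.0700, edgeR).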

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

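The 3 tests of the male transcripts were chosen only after that result was seen, and those of the single genes were fixed before. Of 346 groups of 4 libraries checked for a value far from the other 3, 19 stood out, where chance gives 17.3. In the control, replicate 1 stood apart for CG18179 (26.3 CPM, others 15 to 16.2), Jon25Bi (323 CPM, others 190 to 202), Pex14 (65.3 CPM, others 61.8 to 62.2) and Oamb (16.5 CPM, others 23.4 to 24.7). Control replicate 2 did so for Cda9 (1.26 CPM, others 0.448 to 0.538), Cpr30B (1.26 CPM, others 1.87 to 1.91) and pros (7.72 CPM, others 4.79 to 5.27). For Lcp1 the value of 0.0451 CPM in control replicate 2 lies under the level of 3 counts, and the others were at 0. Control replicate 4 was apart for apolpp (1698 CPM, others 1895 to 1900.3), tim (199.7 CPM, others 230.2 to 235) and cup (659.8 CPM, others 627 to 631). In the mutant, replicate 1 stood apart for BomBc3 (80.3 CPM, others 26.4 to 34.3) and Pex19 (78.0 CPM, others 74.8 to 75.1). Mutant replicate 3 did so for Cyp311a1 (19.0 CPM, others 16.4 to 16.8), santa-maria (28.1 CPM, others 24.8 to 25.4) and Oatp58Db (16.5 CPM, others 11.9 to 12.2). Mutant replicate 2 was apart for CG13032 (2.46 CPM, others 0.0395 to 0.0611) and glob1 (136.9 CPM, others 124 to 126).

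Mutant replicate 2 also held more male transcripts, at 947 CPM over the 59 rows of the male list against 174 to 189 CPM in the other mutants. Rows with too few counts to be tested took 3759 CPM there and 152 to 328 CPM in the controls, and 813 such rows had at least 10 counts there and at most 3 in any other library. The 27 accessory gland rows summed to 486 CPM (36.1 to 41.9 elsewhere) and the 32 testis rows to 460 CPM (117 to 150 elsewhere). Most of the sums elsewhere came from few rows. In control replicate 1 Acp95EF held 951 of 968 accessory gland counts, and twe and Mst85C held 2219 and 746 of 3136 testis counts. The values argue against sperm stored by mated females as the whole source, since the median ratio to the highest other library was 60.7 for accessory gland rows. Where that other library held fewer than 3 counts, the level of 3 counts stood in for it. The values also argue against carry-over from another library of the series, which would hold these transcripts at a higher level. Of the rows, 94.9% were highest in mutant replicate 2. RNA of male flies in the pool is a candidate source, as the median ratio was at least 27.3 in both parts of the list, while carry-over from a library outside the series stays open and no other biological explanation was tested.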

How the results depend on the processing

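The length offset, the counting of identical entries once and the member counts without single libraries were chosen only after the results were seen. Hr78 stayed past the threshold in every alternative run, with log2 fold changes of -0.81 to -0.74. The count of changed genes (2063) stayed within 1.5 times under RLE scaling (2090), upper quartile scaling (2371), no filter (1807), DESeq2 (2313), limma-voom (2087), adjusted p 0.1 (2895), identical entries counted once (2026), the length offset (1546) and each library left out (1476 to 1702). It was 526 with a fold of at least 1.5 and 868 at adjusted p 0.01, because these thresholds are stricter. Of the 2520 alternative values of 168 called genes named by the rule or added later, 2234 kept direction and threshold, 285 were not past it and 1, dpy under the length offset (0.061), reversed, and 108 of the genes stayed past it in every alternative.

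The number of lists past camera's threshold (9) was 0 with an estimated correlation, 1 with fry, 6 with the length offset (4 of them among the 9), 8 with upper quartile scaling, 12 without a filter, 9 in the other fits of all libraries, and 3 to 10 with a library left out (3 without mutant replicate 1, 10 without control replicate 1). With an estimated correlation the adjusted p was 0.498 for the ecdysone list and 0.845 for each of the other 8. With fry it was 0.0745 for the serine proteases and metal homeostasis, 0.126 for the tracheal and oenocyte lists, 0.178 for immune effectors, 0.184 for mitochondrial ribosomal, 0.413 for ribosomal and 0.321 for oxidative phosphorylation genes. Upper quartile scaling gave 0.0759 for oenocytes. The length offset gave 0.141 for tracheal, 0.0865 for ecdysone, 0.891 for oxidative phosphorylation and, in the other direction, 0.438 for ribosomal and 0.263 for mitochondrial ribosomal genes, while muscle and photoreceptors were gained (0.0181 each). Lists gained elsewhere were cuticle (0.0457), Malpighian tubule (0.0484) and male genes (0.0186) without a filter, Malpighian tubule with the replicate block (0.0443) and without control replicate 2, control replicate 4 or mutant replicate 3 (0.0435, 0.0387 and 0.0177), glycolysis (0.0110) and muscle (0.0378) without control replicate 1, and yolk and eggshell genes (0.0114 each) without control replicate 2. With a library left out the adjusted p ran from 0.00113 to 0.207 (oxidative phosphorylation), 0.00490 to 0.0922 (metal), 0.0130 to 0.123 (tracheal), 0.000276 to 0.207 (ribosomal), 0.000408 to 0.0922 (mitochondrial ribosomal) and 0.00894 to 0.123 (oenocytes), with the highest values without mutant replicate 1, or without control replicate 2 for the tracheal and oenocyte lists. Serine protease, immune and ecdysone lists stayed past the threshold without any 1 library. The length offset took the mean log2 fold change of the ribosomal, mitochondrial ribosomal and oxidative phosphorylation lists below 0, but left that of the tracheal list at -0.23 (from -0.29) and of the ecdysone list at -0.36 (from -0.43). Apart from this, the stricter thresholds and the set tests, the cause of lost calls was not tested. Each fit without a library had fewer libraries and called fewer genes (1476 to 1702 against 2063). Calls near the threshold can thus be lost whichever library is left out.

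The replicate numbers do not pair the libraries, since the deviations of same-numbered libraries correlated at 0.21, -0.05, -0.10 and 0.04, and not every library correlated best with its own number. With the replicate block 2405 genes passed (1014 higher, 1391 lower), 1921 of them among the 2063, and the tracheal list had an adjusted p of 0.0850. At these depths changes under 1.5-fold are often missed, and counts of up to 3 members per direction changed with a library left out in many lists.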

Other observations

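All genes and families in the next sentences, and the test of the third chromosome as a whole, were chosen only after the values were seen, whereas the other tests of the length trend, arm 3L and the splits were fixed before their results. Among genes with a mean of at least 100 CPM in either genotype, 28 changed at least 2-fold, 22 lower and 6 higher in the mutant. Many of those that fell are in the digestive lists, among them the misplaced Bace, and others are in the immune or ecdysone list or in none. Outside the lists, CG12374 fell from 3684 ± 1345 to 804 ± 173 CPM (log2 fold change -2.20, standard error 0.29, edgeR adjusted p 0.00300) and Alp9, an alkaline phosphatase gene, from 174 ± 36.9 to 75.1 ± 22.3 CPM (edgeR adjusted p 0.0147). Mgstl, a microsomal glutathione transferase gene, rose from 54.8 ± 3.75 to 125 ± 12.2 CPM (edgeR adjusted p 8.49e-06).

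Of 95 gene families formed by symbol, 5 passed camera with a preset correlation, adjusted over the 95, and none passed with an estimated one (adjusted p = 0.841). The Dscam family had 28 of 31 entries lower, but 26 entries are repeated forms of Dscam1. Genes of complex I subunits (ND) had 7 of 38 higher (adjusted p 0.00233), which the length offset moved to 0.442, and those of cytochrome oxidase (COX) 4 of 14 (0.0210, and 0.248 with the offset). Nucleoporin genes had 5 of 21 lower (0.0210, and 0.115 with the offset), and the dpr genes, neuronal cell surface proteins, had 2 of 20 higher (0.0456, and 0.00786 with the offset).

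The count of 2063 genes was not matched by any other division of the 8 libraries into 4 and 4. Of the 35 splits 1, the real one, gave as many, and the highest other gave 1 gene. Every other split mixes the genotypes, so a difference between them widens the spread within its groups and lowers its count. The splits therefore do not exclude chance, nor a difference in handling that runs with genotype.

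The higher levels of short-transcript lists may reflect a length trend between the libraries. With the length offset the mean log2 fold change of the ribosomal, mitochondrial ribosomal and oxidative phosphorylation lists lost its sign (at most -2.03% of it kept), and all 3 were no longer past the threshold. The offset was fitted to these same libraries, whose slopes run with genotype. It thus removes the average genotype difference of short transcripts whatever its source. The loss therefore shows only that these lists rose no more than other genes of their length. Male RNA in mutant replicate 2 does not account for it, since at least 111% of each mean remained without that library. The choice of scaling stays open. The lowest mean over TMM, RLE and upper quartile scaling was 0.0610, which was to count against it, but this test was found void after the values were seen, since the mean of all genes was 0.006 with TMM, 0.003 with RLE and 0.052 with upper quartile scaling, so neither alternative could lower the lists by their shift. The length slope separates the genotypes, and its relation to depth was not tested, so a technical trend that runs with genotype and a biological change in short transcripts cannot be told from each other here.

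Changes of at least 2-fold were more frequent on arm 3L, which carries Hr78, than on the X and second chromosome arms (3.14% against 1.99%, odds ratio 1.6, 95% interval 1.15 to 2.20, Fisher's exact p 0.00426). The share of all genes past the adjusted threshold on 3L (21.1%) lay within the range of those arms, from 16.8% on 2L to 22.9% on the X. The explanations below therefore concern the 2-fold changes only. Genes are not independent replicates, and close copies can change together or share reads, so the p-values and intervals in this paragraph may be too narrow. A stretch of differing background around Hr78 is argued against by 1% of its 200 tested neighbours changing 2-fold (2 genes, upper bound 7.13 genes, against an excess of 23.5 genes on 3L), where the rest of 3L had 3.38% (Fisher's exact p 0.0841). A background along all of the third chromosome stays open, since the odds ratio for 3R was 1.07 with a 95% interval of 0.761 to 1.5. Digestive genes on 3L also stay open, since the odds ratio without their 102 listed members was 1.42 with an interval of 1.00 to 2.00 (Fisher's exact p 0.0379). The lysozyme genes, which are in the immune list, were not left out, so this test does not remove all digestive genes. After the values were seen, the digestive reading gained a condition on the interval's lower bound, without which 1.42 would have counted against it, and the Hr78 reading gained the comparison with the excess, which did not change it.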
